A study of Homo sapiens with 6 samples.

How the data were processed

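RNA sequencing of HL-60, a human acute myeloid leukaemia cell line, was analysed in 6 libraries. Of these, 3 came from cells carrying a short hairpin RNA against OSGEP and 3 from cells carrying a control hairpin. The labels' protocols give extraction of total RNA, a stranded mRNA library kit and paired-end reads of 150 bp. The deposited values were whole-number read counts per Ensembl gene, 1 table per library, with the same 58302 genes in the same order in all 6. The submitters' processing notes list HISAT2 2.1.0 and featureCounts 1.6.3 and the genome builds GRCh38 and GRCm38, without saying what each was used for. The annotation release, the strand setting of the counting and the treatment of reads with several alignments are not given in the sources used here. Reads of near-identical copies, such as ribosomal protein genes and their processed pseudogenes, can therefore be split in a way that is not known, and reads of overlapping or antisense genes may not be told apart. The study's proteome was not analysed here.

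The total count was 9725775, 10157091 and 8326982 in knockdown libraries 1, 2 and 3 and 9902839, 10025573 and 8414775 in control libraries 1, 2 and 3. Gene symbols, gene types and positions came from GENCODE release 29 on GRCh38, which holds 58039 of the identifiers, and symbols were updated from a table of current names that holds 57532 of them. Neither source held 263 identifiers. Groups and replicate numbers were taken from the sample titles. No label says whether libraries of a group came from separate cultures or whether more than 1 hairpin against OSGEP was used, so p-values measure only the spread between these libraries, which may be technical. In pairs of libraries of 1 group, the chi-square per degree of freedom over genes lay between 10.87 and 27.97. Repeated reads of the same molecules can give such values too, so they do not show that the libraries are separate replicates, and each was treated as 1 without that being settled.

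Differential expression was tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 with group as the only term, TMM normalisation and the default filterByExpr filter (minimum count 10, minimum total count 15), which kept 14018 genes and left out 44284. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Standard errors of log2 fold changes were computed from the fold change and its F statistic. CPM values are TMM-normalised and are given as mean ± SD over the 3 libraries of a group. The common biological coefficient of variation was 35.2%. Ratios of genes with 1 to 3 counts in a whole group carry exact 95% intervals of the counts, which cover counting error only, since reads without molecular identifiers are not independent molecules.

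The main test, 34 gene lists and most alternatives were fixed before the data were examined, and those chosen later are named as such. Of the 34 fixed lists, 33 had at least 5 tested members and were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. For each list the called members were counted over all genes tested and again adjusted over the list alone. The lists cover the KEOPS complex and t6A pathway, cytosolic aminoacyl-tRNA synthetases, other anticodon-loop enzymes, the integrated stress response, endoplasmic reticulum chaperones, heat shock proteins, G1/S, G2/M, cell cycle arrest, pro-apoptotic and anti-apoptotic genes, cytarabine metabolism, DNA repair, primary granules, granulocytic and monocytic differentiation, stem cell genes, ribosome biogenesis, ribosomal proteins, translation factors, nuclear and mitochondrial respiratory genes, glycolysis and hypoxia, cholesterol synthesis, interferon-stimulated genes, NF-kB and cytokine genes, lysosome genes and telomere genes. Of the lists tested, 1 is not reported. Histones and nuclear RNAs served as signs of RNA selection and quality, and erythroid, lymphoid, and epithelial and mesenchymal markers as signs of other cells. Only 1 listed symbol, DDX58 of the interferon list, was not matched.

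Most of the genes named in the report followed a fixed rule. They are OSGEP and its list; of the called genes with a mean CPM of at least 5, a symbol that is not a clone name and groups whose values do not overlap, the 10 with the largest rise and the 10 with the largest fall; of each list, up to 3 called members with a mean CPM of at least 5 and the largest absolute log2 fold change, or, where none was called, up to 2 members with the highest mean CPM; and BCL2, MCL1, MYC, CDKN1A and MPO. The rule named 109 genes, a few of which are not reported.

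The alternatives tried were RLE size factors, library size alone, no filter beyond 1 read, a filter at a mean CPM of 5, the replicate number as a block, each library left out in turn, DESeq2 1.42.0, limma-voom, stricter thresholds, camera with an estimated correlation and fry. A fit on counts divided by 12 and a fit on protein-coding genes alone were added after the data were seen. The steps were tested on simulated counts for the same comparison. Over 13389 simulated genes, 74.2% of the 66 genes changed 4-fold, 47.8% of the 67 changed 2-fold and 9.0% of the 67 changed 1.5-fold were called in the right direction, with 1 false call among 88. At a mean CPM of 20 or more these shares were 100.0%, 79.5% and 20.7%. In simulated random lists of genes drawn independently, camera called the 1 shifted list and 0 of 30 unshifted ones, over 13345 genes. That does not test lists whose members vary together, so it does not bear on the false calls of the real lists.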

Results

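The transcriptome was studied in HL-60, a human acute myeloid leukaemia cell line that grows in suspension. Cells with a short hairpin RNA against OSGEP (3 libraries) were compared with cells with a control hairpin (3 libraries). OSGEP encodes the catalytic subunit of KEOPS, the complex that makes the t6A modification beside the anticodon of tRNAs that read codons starting with A. The study set out to learn what OSGEP does in acute myeloid leukaemia, with proliferation, the cell cycle and apoptosis as the pathways of interest, and its title also names resistance to cytarabine. Total counts per library ran from 8326982 to 10157091, and the mean total of the knockdown libraries was 0.995 of that of the controls. Between 18282 and 19374 genes had at least 1 count in a library. The first principal component, with 51.3% of the variance, placed the knockdown libraries between -36.12 and -32.72 and the control libraries between 31.33 and 37.22.

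OSGEP mRNA was lower in every knockdown library than in any control library. Its expression was 21.18, 23.11 and 20.87 CPM in knockdown libraries 1, 2 and 3 and 49.05, 54.41 and 76.92 CPM in control libraries 1, 2 and 3, a fall from 60.1 ± 14.8 to 21.7 ± 1.21 CPM (SD, n = 3 each). The log2 fold change was -1.47 (SE 0.21), with an edgeR adjusted p of 0.000228. OSGEP (ENSG00000092094) lies on chromosome 14 at 20446411 to 20455105 on the minus strand of GRCh38. APEX1, the adjacent gene on the other strand, was not called, at 253 ± 28.3 CPM in the knockdown and 287 ± 9.54 CPM in the control (log2 fold change -0.18, edgeR adjusted p = 0.403).

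Of the 9 genes of the KEOPS and t6A list, OSGEP fell and the other 8 were not called, both over all genes tested and adjusted over the list alone. The KEOPS subunits TP53RK, TPRKB, LAGE3 and GON7 had log2 fold changes of 0.04, 0.05, 0.29 and -0.16. YRDC, which supplies the threonylcarbamoyl precursor, had 0.11, and OSGEPL1, the mitochondrial relative of OSGEP, had 0.15. CDKAL1 and TRMO, which modify t6A further, had -0.05 and -0.02. As a set the list was not shifted (camera adjusted p = 0.735), and its median of 0.04 and mean of -0.12 differ in sign. Of 27 other enzymes of the anticodon loop, 0 were called by edgeR over all genes or adjusted over the list alone, with 4 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma-voom. Their median of -0.02 became 0.05 with library size alone. The most abundant of these were MTO1, at 104 ± 15.3 CPM in the control and 109 ± 15.8 in the knockdown, and NSUN2, at 87.9 ± 13.6 and 101 ± 16.4 CPM (camera adjusted p = 0.903 for the list).

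**Figure D1:**
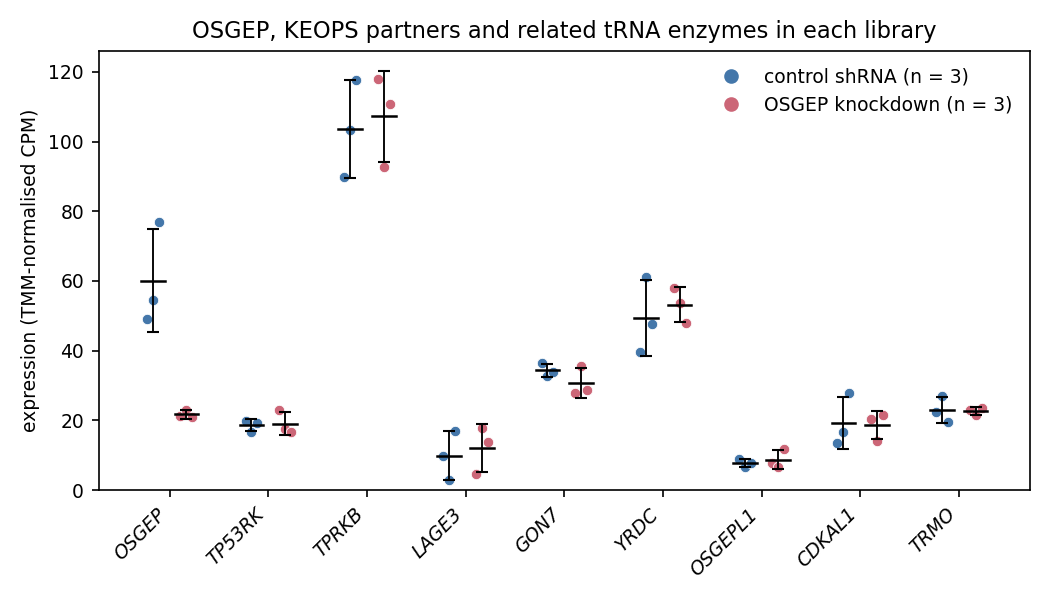
Expression in TMM-normalised CPM of OSGEP, its KEOPS partners and related tRNA enzymes, with 1 point per library, a horizontal bar at the mean and error bars of 1 SD (n = 3 per group). OSGEP sat between 20.87 and 23.11 CPM in the knockdown and between 49.05 and 76.92 CPM in the control, while the other 8 genes were not called.

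Among 14018 genes tested, 1507 changed, 727 higher and 780 lower in the knockdown (edgeR, adjusted p under 0.05). Of the 1507, 823 passed an edgeR adjusted p of 0.01, and 664 changed by at least 1 on the log2 scale, 401 higher and 263 lower. In 1505 of the 1507, every knockdown library lay on the same side of every control library. The control and knockdown values did not overlap for 4052 genes, 28.9% of those tested, where chance gives 10%. With scaling by library size alone the split was 859 higher and 612 lower, since the median log2 fold change moved from -0.008 to 0.061. The count fell to 870 without control 3, 890 without control 2 and 941 without knockdown 3.

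The steepest rises included genes that were near silent in the control. PPARGC1A, a coactivator of mitochondrial biogenesis, had 503 counts in the knockdown libraries and 1 in the controls, a ratio of 482 (exact 95% interval 86.05 to 19060). EPHB2, an ephrin receptor, had 449 and 3 counts, a ratio of 143 (48.7 to 698). CD36, a scavenger receptor for fatty acids and oxidised lipoproteins, rose from 0.787 ± 0.158 to 98.6 ± 18.6 CPM (log2 fold change 6.93, SE 0.28, edgeR adjusted p = 2.26e-10). CADM1, a cell adhesion molecule, rose from 2.65 ± 1.99 to 194 ± 14.5 CPM (6.16, SE 0.31, edgeR adjusted p = 1.95e-09). SRPX, CLMP, the organic anion transporter SLCO2B1, the snRNA pseudogene RNU6-37P, the potassium channel KCNMA1 and TMEM255A stood below 0.3 CPM on average in the control and between 9.98 and 21.02 CPM in the knockdown, with log2 fold changes of 6.28, 6.11, 6.01, 5.84, 5.69 and 5.67.

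Among the falls, metallothioneins, which bind zinc and copper, stood out by size. MT2A fell from 161 ± 13.8 to 8.24 ± 2.44 CPM (log2 fold change -4.29, SE 0.21, edgeR adjusted p = 1.85e-09). MT1G had 418 counts in the control libraries and 3 in the knockdown, a ratio of 145.5 in favour of the control (exact 95% interval 49.5 to 709). ABCA1, which exports cholesterol, fell by 3.45 (SE 0.55). The receptor kinase AXL had a log2 fold change of -3.34 (SE 0.55), the proteoglycan VCAN -3.16 (SE 0.41) and CIITA, the master regulator of MHC class II genes, -3.08 (SE 0.54). The centrosomal gene CEP70 stood at -3.52 (SE 0.58), the long noncoding RNA LINC02367 at -3.04 (SE 0.47) and the calcium channel gene CACNA1A at -3.79 (SE 0.81). The processed pseudogene RPL5P29, which may share reads with RPL5, fell from 80.4 ± 13.97 to 3.24 ± 1.12 CPM (-4.61, SE 0.27).

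Single libraries moved several of these estimates by over 1.5 times, most of them where 1 group held few counts. Without control 2, PPARGC1A stood at 10.34, EPHB2 at 10.19, RNU6-37P at 6.46, KCNMA1 at 6.31, SRPX at 5.68, CLMP at 5.51 and CACNA1A at -2.81 on the log2 scale. Of these, only the CACNA1A call was lost, as it also was with limma-voom, at -3.60, where KCNMA1 was lost too, at 5.45. Without control 1, SRPX stood at 7.99, TMEM255A at 7.40, CADM1 at 6.99, CLMP at 6.83 and SLCO2B1 at 5.41, and without control 3 SLCO2B1 stood at 7.02. Without knockdown 1, ABCA1 stood at -4.96 and CACNA1A at -4.62, and without knockdown 2 MT1G stood at -10.12 and CEP70 at -4.19.

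**Figure D2:**
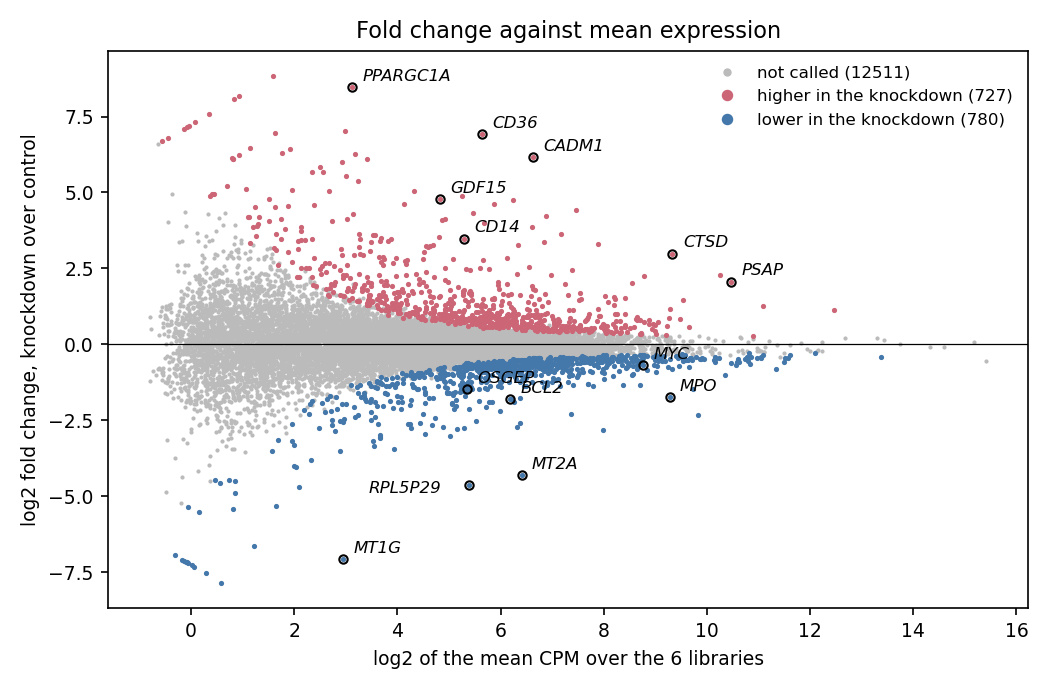
Log2 fold change of the knockdown over the control against the log2 of the mean CPM over 6 libraries, with 1 point per gene tested (edgeR, n = 3 per group). The 727 called rises and 780 called falls are coloured, and circled genes include CD36 at 6.93, CTSD at 2.99, MPO at -1.74 and MT2A at -4.29.

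Across the 33 lists tested, camera found 13 shifted, 6 up and 7 down. With a correlation estimated for each list, camera called 0 of the 33, with adjusted p-values from 0.0661 to 0.408 among the 13 and 8 lists at an unadjusted p under 0.05, while fry called 15, the 13 and 2 more, of which 1 is the list not reported.

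Genes of DNA replication and S phase entry fell together. Of 48 measured, 21 fell and 0 rose over all genes tested (26 and 0 adjusted over the list alone), with a median log2 fold change of -0.45 and a camera adjusted p of 3.04e-09 (adjusted p = 0.0661 with an estimated correlation). The replication kinase gene CDC7 fell from 60.6 ± 5.15 to 25.5 ± 11.6 CPM, a log2 fold change of -1.25 (SE 0.26). GINS2, a subunit of the replicative helicase, fell by 1.09 (SE 0.23), and the G1 kinase CDK6 by 1.02 (SE 0.14). Mitotic genes had a smaller median fall, and the difference between the lists was not tested. Of 46, 5 fell and 0 rose (6 and 0 adjusted over the list alone), with a median of -0.19 and a camera adjusted p of 0.0215 (adjusted p = 0.245 with an estimated correlation). AURKB, KIF11 and CDK1 fell by 0.79, 0.60 and 0.57. The list lost its camera call without knockdown 3, at a median of -0.12, and with counts divided by 12, at -0.16. AURKB lost its own without knockdown 3 (-0.75), control 2 (-0.81) or control 3 (-0.71), and CDK1 without any 1 of the controls (-0.58, -0.58 and -0.57).

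DNA repair genes also fell. Of 36, 7 fell and 0 rose, as did 7 and 0 adjusted over the list alone, with a median of -0.37 and a camera adjusted p of 6.59e-05 (adjusted p = 0.108 with an estimated correlation). The helicase gene BLM fell by 1.03 (SE 0.20) and the Fanconi gene FANCI by 0.66 (SE 0.15). FANCI lost its call without knockdown 3 (-0.60) or control 3 (-0.57).

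CDK inhibitors and arrest genes went both ways, 4 up and 4 down of 19 (5 and 6 adjusted over the list alone), and the list was not shifted (camera adjusted p = 0.715). CDKN1A, which encodes p21, rose from 14.6 ± 1.16 to 50.2 ± 11.5 CPM (log2 fold change 1.78, SE 0.24, edgeR adjusted p = 8.81e-05), and BTG2, an antiproliferative gene, rose by 1.89 on the log2 scale (SE 0.22). CDKN2D, which encodes p19, fell by 1.99 (SE 0.30). With fry, this list was called up.

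Apoptosis genes did not move one way. Of 28 pro-apoptotic genes, 2 rose and 2 fell, and the same counts held adjusted over the list alone (median 0.15, camera adjusted p = 0.715). CASP2 fell from 102 ± 4.79 to 51.2 ± 1.93 CPM (log2 fold change -0.99, SE 0.15), the BH3-only gene BCL2L11 fell by 0.72 (SE 0.20) and the TRAIL receptor TNFRSF10B rose by 0.95 (SE 0.21). Of 14 anti-apoptotic genes, 2 rose and 1 fell (5 and 1 adjusted over the list alone; median 0.35, camera adjusted p = 0.0855). BCL2 fell from 113 ± 19.8 to 32.7 ± 8.39 CPM (-1.79, SE 0.20, edgeR adjusted p = 1.92e-05), while its relatives BCL2A1 and BCL2L1 rose, by 2.26 (SE 0.34) and 1.14 (SE 0.34). MCL1 was not called by edgeR, at 223 ± 12.8 CPM in the control and 276 ± 30.9 in the knockdown (0.31, edgeR adjusted p = 0.115), but passed with DESeq2 (0.33). BCL2L11 kept its call only in the fit without knockdown 1 (-0.79 to -0.53 in the other 5). BCL2L1 lost its call without knockdown 1 (1.15), knockdown 3 (1.05), control 1 (0.86) or control 3 (1.15), and TNFRSF10B without knockdown 3 (0.75) or control 2 (0.81).

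Genes that handle cytarabine, the nucleoside drug used in acute myeloid leukaemia, were not shifted as a list (median -0.30, camera adjusted p = 0.0736). Of 23, 1 rose and 4 fell (1 and 5 adjusted over the list alone). The nucleoside transporter SLC29A2 fell from 63.8 ± 3.37 to 22.9 ± 4.61 CPM (log2 fold change -1.48, SE 0.20, edgeR adjusted p = 0.000111). The transporter SLC28A3 fell by 2.20 (SE 0.66), and NT5C2, a nucleotidase that acts on nucleoside drug phosphates, rose by 1.51 (SE 0.37). Outside the naming rule, the remaining called falls were SLC29A1 at -0.51 (SE 0.11) and DCK at -0.60 (SE 0.13). NT5C2 lost its call without control 2 (1.44) or control 3 (1.28). SLC28A3 kept its call only in the fit without knockdown 3, at -2.82, with -2.45 to -1.67 in the other 5, and lost it with library size alone (-2.15). Without knockdown 1 the list itself was called down (median -0.26).

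Genes of primary granules, made at the promyelocyte stage, fell. Of 12 measured, 6 fell and 2 rose (8 and 3 adjusted over the list alone), with a median of -0.72 and a camera adjusted p of 0.000994 (adjusted p = 0.140 with an estimated correlation). MPO, which encodes myeloperoxidase, fell from 954 ± 16.1 to 286 ± 10.03 CPM (log2 fold change -1.74, SE 0.09, edgeR adjusted p = 4.03e-09). AZU1 fell by 2.57 (SE 0.19) and RNASE2 by 1.53 (SE 0.20). The granulocytic list was called up on 4 rises and 4 falls among 22 (10 and 4 adjusted over the list alone), with a median of 0.29 and a camera adjusted p of 0.0269 (adjusted p = 0.245 with an estimated correlation). ITGAX and S100A9 rose by 2.07 and 1.91. Outside the naming rule, the 4 falls were FUT4 at -1.43 (SE 0.19), CSF3R at -1.24 (SE 0.17), GFI1 at -0.65 (SE 0.12) and MNDA at -0.47 (SE 0.12). The granulocytic list lost its call without knockdown 2 (median 0.32), with a mean CPM filter of 5 (0.30) and with counts divided by 12 (0.26). S100A9 was lost without knockdown 2 (1.32), knockdown 3 (2.00), control 2 (1.55) or control 3 (1.92) and with limma-voom (1.93).

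Monocytic differentiation genes split, with 6 up and 7 down among 22 (7 and 9 adjusted over the list alone, median -0.29, camera adjusted p = 0.543). CD14, the lipopolysaccharide co-receptor, rose from 6.43 ± 0.661 to 72.1 ± 8.28 CPM (log2 fold change 3.48, SE 0.22, edgeR adjusted p = 2.60e-08), whereas VCAN was among the steepest falls. Of 13 stem and progenitor genes, 3 fell and 0 rose, as did 3 and 0 adjusted over the list alone, with no shift of the list (median -0.19, camera adjusted p = 0.389). These were FLT3 at -1.46 (SE 0.28), MYB at -1.39 (SE 0.17) and GATA2 at -1.12 (SE 0.32). GATA2 lost its call in every fit that left out 1 library (-1.24 to -0.97) and with library size alone (-1.05).

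The integrated stress response rose. Of 33 targets of ATF4 and its partners, 17 rose and 1 fell (21 and 1 adjusted over the list alone), with a median of 0.76 and a camera adjusted p of 7.13e-11 (adjusted p = 0.0661 with an estimated correlation). The stress cytokine GDF15 rose from 1.96 ± 1.27 to 54.8 ± 9.47 CPM (log2 fold change 4.77, SE 0.38, edgeR adjusted p = 3.99e-07). SLC7A11, the cystine transporter, rose from 4.19 ± 0.371 to 84.1 ± 6.61 CPM (4.33, SE 0.22). ADM2 rose by 4.59 on the log2 scale (SE 0.88), a call that limma-voom did not make (4.85), and stood at 3.99 without control 1. Of 23 cytosolic aminoacyl-tRNA synthetases and their scaffolds, 9 rose and 0 fell (9 and 2 adjusted over the list alone), with a median of 0.20 and a camera adjusted p of 0.0269 (adjusted p = 0.192 with an estimated correlation). CARS1, SARS1 and MARS1 rose by 0.99, 0.97 and 0.96. The list lost its call without knockdown 1 (median 0.22) or control 1 (0.26).

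The endoplasmic reticulum and heat shock lists were not shifted. Of 27 chaperone and folding genes, 2 rose and 1 fell (3 and 2 adjusted over the list alone; median -0.07, mean -0.02, tested upward, camera adjusted p = 0.969). SYVN1 rose by 0.71, HERPUD1 rose by 0.67 and XBP1 fell by 0.46. SYVN1 lost its call without knockdown 1 (0.55), knockdown 2 (0.76), control 1 (0.51) or control 3 (0.75), HERPUD1 without knockdown 3 (0.60), control 1 (0.66) or control 3 (0.59), and XBP1 without knockdown 3 (-0.40) or control 2 (-0.40). Of 17 heat shock genes, 1 rose and 0 fell, in both adjustments (median 0.10, camera adjusted p = 0.731). It was the co-chaperone BAG3, at 1.35 (SE 0.32), lost without knockdown 3 (1.30) or control 3.

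Ribosomal protein transcripts fell by small amounts. Of 77, 27 fell and 0 rose (47 and 0 adjusted over the list alone), with a median of -0.30 and a camera adjusted p of 6.10e-08 (adjusted p = 0.4003 with an estimated correlation). Their summed expression was 65160 CPM in the control and 51660 CPM in the knockdown. RPS23, RPL26 and RPL31 fell by 0.73, 0.65 and 0.61. Each value is uncertain, since these genes may share reads with many pseudogenes. MYC fell from 536 ± 43.5 to 333 ± 37.8 CPM (log2 fold change -0.69, SE 0.11, edgeR adjusted p = 0.000603). It was the 1 called gene among 40 of the ribosome biogenesis list, in both adjustments (median -0.14, camera adjusted p = 0.155), though the list was called down without knockdown 1 (median -0.18). Of 37 translation factors, 2 rose and 5 fell, in both adjustments, with no shift (camera adjusted p = 0.666) and a median of -0.03 that became 0.04 with library size alone. EIF1 rose by 0.82 (SE 0.12), and EEF1A1 and EIF3E fell by 0.57 (SE 0.10) and 0.55 (SE 0.11).

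Lysosome and autophagy genes rose. Of 32, 14 rose and 0 fell (18 and 1 adjusted over the list alone), with a median of 0.59 and a camera adjusted p of 2.26e-08 (adjusted p = 0.0661 with an estimated correlation). Their summed expression was 3066 CPM in the control and 6774 CPM in the knockdown. The protease gene CTSD rose from 145 ± 13.0 to 1144 ± 171 CPM (log2 fold change 2.99, SE 0.12, edgeR adjusted p = 2.49e-10). PSAP, the saposin precursor, rose from 547 ± 38.9 to 2288 ± 255 CPM (2.07, SE 0.10), and the autophagosome gene GABARAPL1 rose by 2.15 (SE 0.31).

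Cholesterol and fatty acid synthesis genes fell. Of 26, 15 fell and 0 rose (16 and 0 adjusted over the list alone), with a median of -0.81 and a camera adjusted p of 1.52e-08 (adjusted p = 0.206 with an estimated correlation). The sterol carrier STARD4 fell from 34.8 ± 5.86 to 11.4 ± 0.171 CPM (log2 fold change -1.62, SE 0.25, edgeR adjusted p = 0.000422), and the desaturase SCD fell from 594 ± 9.82 to 238 ± 81.8 CPM (-1.32, SE 0.19). Glycolysis and hypoxia genes were called down on 6 falls and 2 rises among 28 (7 and 2 adjusted over the list alone), with a median of -0.17 and a camera adjusted p of 0.0142 (adjusted p = 0.408 with an estimated correlation). NDRG1, BNIP3 and PDK1, known targets of HIF1A and not glycolytic enzymes, fell by 1.97 (SE 0.22), 1.85 (SE 0.20) and 1.65 (SE 0.26). The list lost its call without knockdown 2 (median -0.18).

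Nuclear-encoded respiratory chain genes rose slightly. Of 44, 7 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.29 and a camera adjusted p of 0.000218 (adjusted p = 0.127 with an estimated correlation). NDUFA8, NDUFA9 and COX6A1 rose by 0.75, 0.72 and 0.57. NDUFA8 kept its call only in the fit without knockdown 1 (0.65 to 0.83 in the other 5), NDUFA9 only in the fit without knockdown 3 (0.62 to 0.77 in the other 5), and COX6A1 lost it without knockdown 3 (0.54) or control 1 (0.49). Of 15 mitochondrially encoded transcripts, 1 fell, MT-CO3 at -0.41 (SE 0.08), and 0 rose (3 and 0 adjusted over the list alone), and the list was not shifted (median 0.02, mean -0.03, camera adjusted p = 0.969).

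Inflammatory genes rose. Of 20 NF-kB and cytokine genes, 5 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 0.78 and a camera adjusted p of 2.34e-05 (adjusted p = 0.168 with an estimated correlation). The chemokine CCL2 rose from 5.35 ± 2.22 to 146 ± 10.97 CPM (log2 fold change 4.76, SE 0.24, edgeR adjusted p = 2.31e-09). IL1B rose by 2.86 (SE 0.33) and TNFAIP2 by 1.05 (SE 0.17). Of 27 interferon-stimulated genes, 1 fell and 0 rose (0 and 0 adjusted over the list alone), with a camera adjusted p of 0.607 and a median of -0.03 that became 0.04 with library size alone. HERC5, the 1 called gene, at -0.78 (SE 0.24), kept its call without knockdown 2 but lost it in the other 5 fits without 1 library (-0.90 to -0.63), with RLE factors (-0.76), with library size alone (-0.71) and with limma-voom (-0.76). Of 14 telomere genes, 1 rose and 0 fell (1 and 1 adjusted over the list alone; median -0.15, camera adjusted p = 0.685). It was NOP10, at 0.56 (SE 0.14), lost without knockdown 3 (0.59), control 1 (0.54) or control 2 (0.51).

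**Figure D3:**
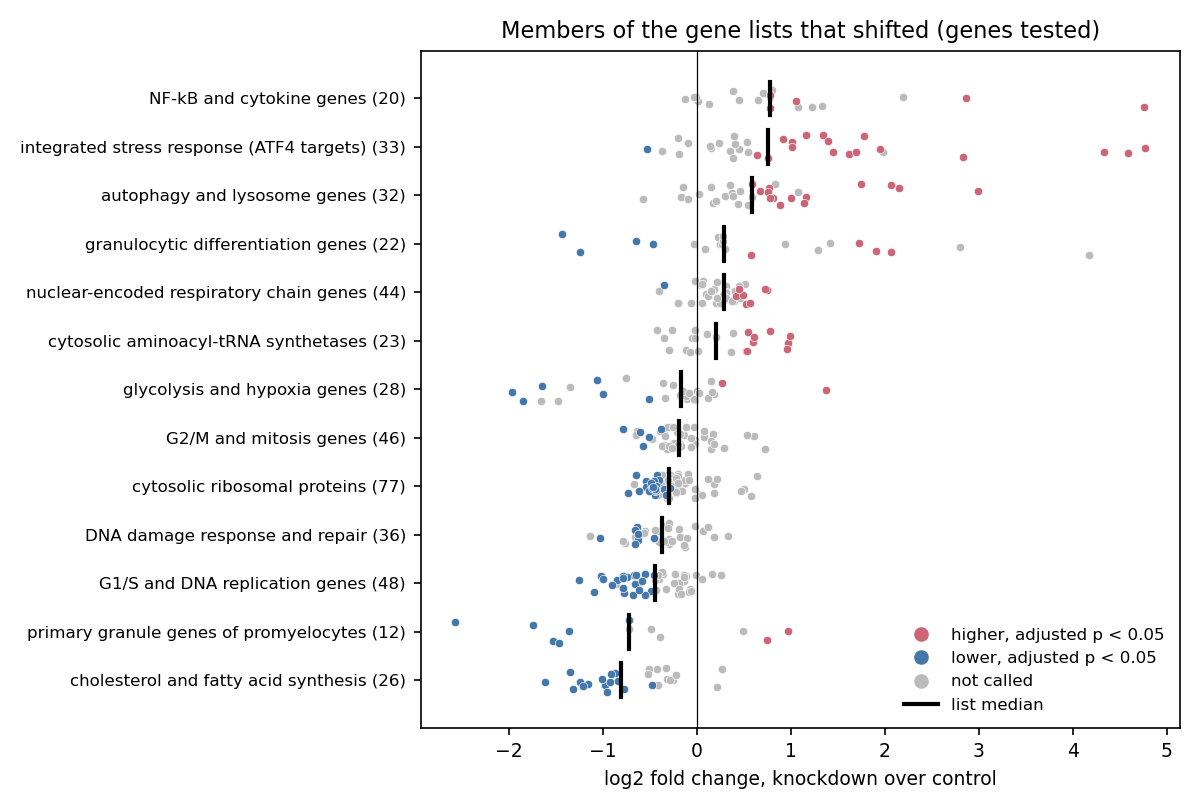
Log2 fold change of each tested member of the 13 lists that camera called, with 1 point per gene, called genes coloured and a black bar at the list median (n = 3 libraries per group). Medians run from -0.81 for cholesterol and fatty acid synthesis to 0.78 for NF-kB and cytokine genes.

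Signs of RNA selection and of other cell types were read beside these groups. Mitochondrial transcripts took 17.12% to 20.37% of the counts, with both groups in that range. Nuclear retained RNAs took 0.223% to 0.236% of the counts in the knockdown and 0.290% to 0.331% in the control, without overlap. Of 8, 3 fell and 0 rose (4 and 0 adjusted over the list alone; median -0.22, camera adjusted p = 0.511), namely MALAT1 at -0.64 (SE 0.09), OIP5-AS1 at -0.81 (SE 0.12) and SNHG14 at -1.07 (SE 0.29). SNHG14 kept its call only in the fit without knockdown 1 (-1.15 to -0.82 in the other 5). Pseudogenes took 9.06% to 9.19% of the counts in the knockdown and 9.90% to 10.05% in the control.

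Replication-dependent histones, whose transcripts mostly lack poly(A) tails, took from 0.0518% of the counts in knockdown 1 to 0.264% in knockdown 2. Of 18, 0 were called by edgeR in either adjustment, with 2 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma-voom (camera adjusted p = 0.775, median 0.45). The most abundant, H1-4, stood at 319 ± 132 CPM in the control and 391 ± 268 in the knockdown, and H2BC4 at 149 ± 66.5 and 207 ± 134. Without knockdown 1 the list was called up (median 0.89), and without knockdown 2 its median was -0.26. H2BC4 was called without knockdown 1 (0.89) and with no filter on low counts (0.46).

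Markers of other cells stayed low. Lymphoid markers took at most 0.0107% of the counts. Of 5 tested, PAX5 rose by 3.64 (SE 0.65), or 5.07 without control 3, and NKG7 fell by 1.88 (SE 0.17), in both adjustments (median -0.04, mean 0.46, camera adjusted p = 0.969). The median became 0.03 with library size alone. Epithelial and mesenchymal markers took at most 0.00853% of the counts. Of 8, 1 rose and 0 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.222). It was CDH1, at 1.59 (SE 0.42), which kept its call without knockdown 2 and lost it in the other 5 fits without 1 library (at most 1.69). Only 3 erythroid and megakaryocytic markers passed the filter, too few for the set test, and 0 were called by edgeR, DESeq2 or limma-voom or had an unadjusted p under 0.05 (edgeR). EPOR, the most abundant, stood at 16.5 ± 0.716 CPM in the control and 10.8 ± 2.19 in the knockdown.

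**Figure D4:**
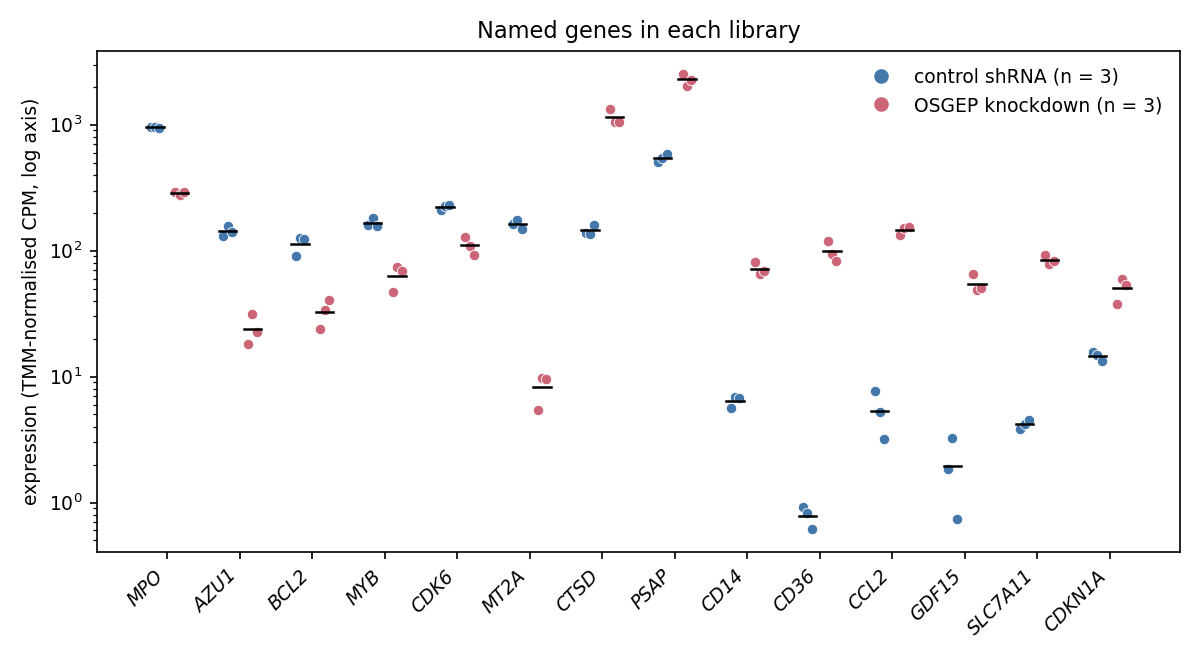
Expression in TMM-normalised CPM on a log axis of 14 named genes, with 1 point per library and a bar at the group mean (n = 3 per group). For each gene the knockdown libraries lie on 1 side of the control libraries, as for MPO at 274.5 to 293.1 against 935.9 to 966.7 CPM.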

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

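The fits on divided counts and on protein-coding genes were chosen after the data were seen. The count of changed genes, 1507 in all, ranged from 870 to 1624 when single libraries were left out, with 445 to 726 higher and 423 to 898 lower. It was lower by over 1.5 times without control 3 (870), control 2 (890) or knockdown 3 (941), each with fewer samples. Stricter thresholds left 823 genes at an adjusted p under 0.01, 664 with an absolute log2 fold change of at least 1, and 910 with glmTreat against a 1.2-fold change. RLE factors gave 1452, library size alone 1471, no filter 1649, a mean CPM of at least 5 gave 1548, DESeq2 1874, limma-voom 1553, counts divided by 12 gave 1632 and protein-coding genes alone 1530. No called gene reversed its sign in any of these fits. OSGEP passed in every fit in which its value was read, which leaves out counts divided by 12. Its log2 fold changes ran from -1.60 to -1.25 when single libraries were left out. The count of shifted lists was 11 to 15 without single libraries and 15 with fry, but 0 with an estimated correlation (8 at an unadjusted p under 0.05), and the cause was not tested. With the replicate number as a block the count of changed genes was 1072, 519 higher and 553 lower, and that of lists 13. Among the named genes, SYVN1, HERPUD1, BCL2L1, SLC28A3, S100A9, GATA2, NDUFA8, NDUFA9, HERC5 and CDH1 lost their calls with the block. Samples with the same number did not deviate together (correlations -0.21, -0.09 and -0.04, and 0 of 6 libraries correlated best with their own number). That does not exclude a day or culture shared by number. Total counts were lowest in library 3 and highest in library 2 of both groups. Over the named genes and the settings other than counts divided by 12, 1399 values kept their side of the threshold, 103 lost it, 3 gained it and 0 reversed. Over lists these were 464, 21, 5 and 0. Weakly expressed genes were measured with less precision, of which depth is 1 part: at a mean count of 14.2 in the control and 14.3 in the knockdown the coefficient of variation was 77.5% and 89.9%, against 11.4% and 16.4% at 889 and 898.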

Other observations

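The groups of NRF2, metallothionein, MHC class II and macrophage lipid genes, and the tests of admixture, of depth, of pseudogenes against their parents, of the replicate spread and of zinc, and the fit on counts divided by 12, were chosen after the results were seen. Of 25 NRF2 targets, which detoxify and handle iron and thiols, 17 rose and 1 fell (edgeR), and their summed expression was 5647 CPM in the control and 11230 CPM in the knockdown, of which FTL alone made up 3551 and 7751 CPM. HMOX1 rose from 1.42 ± 1.65 to 33.7 ± 1.95 CPM (log2 fold change 4.62, SE 0.54) and NQO1 from 12.3 ± 6.31 to 182 ± 38.8 CPM (3.88, SE 0.31). The ferritin chains FTH1 and FTL rose by 1.49 (SE 0.13) and 1.13 (SE 0.08), although ferritin reads may be shared with pseudogenes. GSR, which reduces glutathione, fell by 0.96. Of the 25, 2 are also on a list fixed before. In the integrated stress response, ATF4 itself rose by 1.01 (SE 0.10).

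Of 9 MHC class II genes, 8 fell and 0 rose (edgeR), with a summed expression of 2239 CPM in the control and 424 CPM in the knockdown. Of the 9, which include CIITA, 3 are also on a list fixed before. CD74 fell from 1511 ± 79.9 to 303 ± 47.1 CPM (-2.32, SE 0.11), HLA-DRA stood at -2.80 (SE 0.17) and HLA-DPA1 at -3.02 (SE 0.27), alongside their regulator CIITA. Of 5 metallothioneins, 3 fell and 0 rose, from a summed 204 to 15.0 CPM. Of 23 scavenger receptor and macrophage lipid genes, 13 rose and 2 fell, and 1 of them is on a fixed list. PLA2G7 rose from 15.7 ± 2.85 to 338 ± 34.5 CPM (4.42, SE 0.16), GPNMB from 413 ± 26.3 to 2033 ± 296 CPM (2.30, SE 0.11) and ACP5 from 11.8 ± 4.22 to 224 ± 32.6 CPM (4.24, SE 0.23), while ABCA1 and LPL fell.

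Of the 10 splits of the 6 libraries into 3 and 3, 1 split, the real one, called 1507 or more genes with edgeR. The highest other called 0, with 192 to 726 genes at an unadjusted p under 0.05 in the others, and at most 55 with DESeq2 and 0 with limma-voom. For lists, 1 split, the real one, shifted 13 or more, and the highest other 7. With 10 splits the share cannot be under 0.05.

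The first pattern is the rise of scavenger receptor and macrophage lipid genes in the knockdown. This list was chosen after the results were seen, and camera with an estimated correlation did not call it (adjusted p = 0.0888). Monocytes or macrophages mixed into the cultures would bring CD74 and HLA-DRA, 2 of their abundant transcripts, but CD74 stood at -2.32 and HLA-DRA at -2.80 on the log2 scale. In the knockdown CD74 held 303 CPM in all, beside 2033 CPM of GPNMB, and both groups had nearly equal depth (ratio of mean totals 0.995), so the tables argue against both explanations. Monocytic differentiation of the knockdown cells stays open as a hypothesis. It may go with a slower cycle, and the mitotic list was lower (camera adjusted p = 0.0215), a call lost without knockdown 3 (median -0.12), with counts divided by 12 (-0.16) and with an estimated correlation (adjusted p = 0.245). The monocytic list itself was not shifted, and its members went both ways: CD14 rose while CD74, HLA-DRA and VCAN fell.

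The second pattern is the change of 107 processed and other pseudogenes, 33 higher and 74 lower. Reads of a parent gene placed on its pseudogene could account for part. Over 81 with a tested parent, the median absolute difference in log2 fold change from the parent was 0.32 (bootstrap 95% interval 0.24 to 0.48), beside 0.40 for unchanged pseudogenes, but for 45 of the 81 the parent was not called and for 10 its value had the opposite sign. Transcription of an overlapping gene is argued against, since 0.9% of the 107 (exact 95% interval up to 5.1%) overlapped a gene changed in the same direction. For 6, the ratio to the parent differed between the groups (limma, adjusted p under 0.05 over 1233 pairs). They were RPL5P29 (-4.61, RPL5 -0.49), RPL13AP20 (-2.70, RPL13A -0.08), HINT1P1 (2.84, HINT1 -0.49), COX5AP2 (2.48, COX5A 0.06), SNRPEP2 and RPA2P3. SNRPEP2 and RPA2P3 were weak, at 7.56 and 1.83 CPM in the control and 0.46 and 0 CPM in the knockdown, and carry little weight. For the others, the difference argues against misplaced reads as their whole cause. No biological explanation was tested for these 6 pseudogenes.

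The third pattern is the replicate spread of weakly expressed genes. Few independent molecules behind the reads may account for it. In bins of 10 to 20, 20 to 40 and 40 to 80 counts, the variance was 8.78 to 8.89 times the mean in the control and 12.03 to 13.42 times in the knockdown, so that the highest ratio was at most 1.12 times the lowest. Simulated libraries with 12 reads per molecule gave 11.06 to 12.39, and with 1 read per molecule 0.93 to 1.06. These simulated ratios follow from their settings, so they check only the computation. The squared coefficient of variation fell at least 3.66 times over the same bins. It is computed from the same variances, so this is the same observation in another form. Variation in proportion to expression would keep it level, and is argued against as the main cause at these counts.

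A hypothesis from the biology of t6A, that mRNAs rich in codons starting with A lose abundance when OSGEP falls, was tested across genes, which are not independent replicates. Over 9242 protein-coding genes, the partial Spearman correlation of that codon share and the log2 fold change, with the GC content of the coding sequence held fixed, was 0.003 (bootstrap 95% interval -0.017 to 0.023), and without that control it was -0.056. The tables argue against such a relation at the level of mRNA. Less zinc sensed by MTF1 was tested as the source of the metallothionein fall. SLC30A1, another MTF1 target, rose by 0.60 (SE 0.14, edgeR adjusted p = 0.00891), higher in each of the 3 knockdown libraries than in any control, which argues against it.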
